A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

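The series holds 6 Affymetrix arrays of biotin-labelled cRNA made from total RNA of mixed h+ and h- fission yeast cultures, 3 from YEPD and 3 from YEPME. The authors deposited log2 values per probe set, made with RMA and handled in Partek per the submitters' processing notes. RMA corrects background, normalizes quantiles and summarises the probes of a probe set. Versions, settings and whether the 6 arrays were normalized together are not given in the sources used here. The replicates are labelled biological, and the small number of arrays limits the precision. The p-values measure the spread between arrays that each fit leaves. With no block, that spread includes the offset between replicate 1 and the other replicates described below. Within replicates 2 and 3, it is the spread of 2 arrays per medium alone. Neither is a clean measure of the spread between independent cultures.

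The values cover 10924 probe sets, of which 166 are controls. The platform annotation gave S. pombe genes for 2914 probe sets with 1 gene and 20 with several, S. cerevisiae genes for 2600, and no gene for 5224, which stay unnamed here. The genes were matched to the RefSeq annotation ASM294v3 through their gene numbers, and 3 of them only through their symbol; this table was used for names and for which genes lie nearest the chromosome ends, not for coordinates. The fits ran on the 2896 S. pombe genes with a probe set of their own. For the 14 genes with more than 1 such probe set, the set with the highest mean over the 6 arrays stood for the gene. S. cerevisiae probe sets served as background: a gene was called above background where the mean of either group exceeded their 95th percentile, as 2863 genes did. The filter tried as an alternative asked for this on at least 3 arrays and kept 2870 genes. That percentile was 5.60 and 5.59 on the replicate 1 arrays and 4.78 to 4.81 on the other 4, against medians of 10.22 to 10.31 for the S. pombe genes.

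Groups were taken from the medium named in each sample's growth label, and replicate numbers from the titles. The test chosen before the data were examined was limma (lmFit and eBayes, two-sided, Benjamini-Hochberg) on the log2 values of all 6 arrays, with no block. A gene passed at an adjusted p under 0.05, and the 2-fold count added a log2 difference of at least 1. Gene lists, also fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Lists needed 5 measured members, which 27 of the 28 lists had. Of the list members, 10 entered through an older synonym. Of these, ape4 (listed as aap1) in the nitrogen list and fbh1 (listed as fdh1) in the glucose-repressed list may not be the genes meant. Without all 10, the adjusted camera p with the batch as a block went from 0.00690 to 0.00146 for the nitrogen list and from 0.00609 to 0.00146 for the glucose-repressed list (adjusted p = 0.328 and 0.176 with an estimated correlation).

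Arrays of the same replicate number deviated together from their group means, with correlations across genes of 0.853, 0.835 and 0.836 for numbers 1, 2 and 3, so the numbers pair the arrays by the rule used here. Pairs of unlike numbers 2 and 3 gave 0.816, because most of the shared deviation lies between replicate 1 and the other 2 numbers. The replicate 1 arrays hold values of up to 10 digits and the others of up to 6, and their distributions differ, so that replicate 1 of both media forms a batch of its own. After seeing this, fits with the batch as a block and within the 4 arrays of replicates 2 and 3 were added. The estimate of a gene's difference is the same with and without a block, and only the spread it is set against changes. A model with a separate difference in each batch tested whether the batches differed.

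The genes named were chosen by a rule written before the data were examined. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap and whose higher mean lies above background. It adds up to 4 members of each list past the threshold and up to 2 with the highest level not past it. It also adds all measured P cell, M cell and DIPSY genes, ste11 and mei2. The rule was repeated on the 2 added fits, with groups required not to overlap within each batch. Genes outside it are named as chosen after their values were seen.

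Alternatives planned before the data were examined were the replicate number as a block, arrays centred on their median, quantile normalization over the S. pombe probe sets, a filter on dim genes, the mean of a gene's probe sets, every annotated S. pombe probe set, eBayes with trend and robust settings, an adjusted p under 0.01, treat at 1.5-fold, and leaving out each array. Unnamed probe sets have no species here and could not join the fit of every probe set; they were tested separately. The code was tested on simulated data with 50 genes at each of 4 sizes among the 2896. The simulated arrays kept the real level offsets between batches, but each simulated difference between media was the same in both batches. The rates below therefore do not cover genes whose difference departs between the batches. Without a block it recovered 2% of genes changed by 0.5 on the log2 scale and 36%, 82% and 94% of those changed by 1, 2 and 3, with 0 false calls. With the batch as a block it recovered 92%, 96%, 100% and 100%, with 15 false calls, and within replicates 2 and 3 98%, 100%, 100% and 100%, with 10 false calls. R 4.3.3 and limma 3.58.1 made the fits, and Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 the joins and plots. Scanner files were not used here.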

Results

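Gene expression of the fission yeast Schizosaccharomyces pombe was measured on Affymetrix arrays in mixtures of cells of opposite mating type. The h+ strain YHL6381 (P cells) and the h- strain SPQ-01 (M cells) were grown apart in YEPD at 30 °C to an OD600 of 5.0, combined in equal parts, and kept for 90 min in fresh YEPD or in YEPME. The series concerns sexual flocculation, the clumping of cells of opposite mating type, and its design text calls the YEPME mixtures flocculated and the YEPD mixtures not flocculated. The comparison asks which transcripts differ between the 2 media. Each medium had 3 arrays, labelled as biological replicates 1 to 3, and this small number limits the precision of every value below. The sample labels attach the code YSD to YEPD and YSM to YEPME, whereas the design text attaches them the other way round. The groups here follow the medium named for each sample, and every sign would turn if the codes in the design text held instead. The strain label of the YEPME samples also reads diploid, while their other labels describe a mixture of haploid strains.

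In YEPME, single genes for a stress kinase, an autophagy factor, the uracil response, meiosis and cell adhesion were higher, and some genes for ribosomal proteins and ribosome assembly were lower, 13 of 119 and 7 of 33. srk1 (SPCC1322.08), a kinase of the Sty1 stress pathway, rose most among genes past the test, by 1.59 ± 0.21 on the log2 scale (SE), from a mean log2 level of 8.80 ± 1.52 (SD, n = 3) to 10.38 ± 1.48. The autophagy factor gene atg101 (SPAC25H1.03) rose by 1.16 ± 0.07, mug57 (SPBC146.10) by 1.13 ± 0.07, gut2 (SPCC1223.03C), for mitochondrial glycerol-3-phosphate dehydrogenase, by 1.05 ± 0.11, and urg1 (SPAC1002.19), a uracil-responsive gene, by 1.02 ± 0.12. The ribosomal protein gene rps1401 (SPAC3H5.05C) fell from 12.63 ± 0.04 to 11.58 ± 0.16 (SD, n = 3), a difference of -1.05 ± 0.07 (SE), and nop16 (SPBC1539.10), for a ribosome assembly factor, had a difference of -0.94 ± 0.13. These calls come from limma with the array batch as a block, chosen after the arrays were seen to split into batches, which put 22 genes higher and 38 lower at an adjusted p under 0.05. The lowest adjusted p was 0.0197, and 5 of the higher and 1 of the lower genes differed at least 2-fold. This fit takes the same difference for both batches. However, mug57, gut2, urg1, rps1401 and nop16 were among the genes whose difference departed between the batches in the interaction test below. In replicate 1 and over replicates 2 and 3, urg1 differed by 0.67 and 1.19 and nop16 by -1.32 and -0.75. The genes srk1 (1.48 and 1.64) and atg101 (1.32 and 1.08) did not pass that test. With limma on the same 6 arrays and no block, the test chosen before the data were examined, 0 genes passed, 32 had an unadjusted p under 0.05, and the lowest adjusted p was 0.48. With the replicate number as a block, limma also called 0 genes, with 317 at an unadjusted p under 0.05 and a lowest adjusted p of 0.177. The batch-blocked calls need all 4 arrays of replicates 2 and 3: without any 1 of these, 0 genes passed limma and 283 to 391 had an unadjusted p under 0.05.

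The batch sets replicate 1 of both media apart from replicates 2 and 3. Over all probe sets, the 2 replicate 1 arrays correlated at 0.994 and the other 4 at 0.998 to 0.999, whereas pairs across the batches correlated at 0.976 to 0.981. The level of 2056 genes differed between the batches, and 439 of these differed at least 2-fold, 203 higher and 236 lower in replicate 1. Among the largest, picked after their values were seen, ght1 and ght4, for hexose transporters, were higher in replicate 1 by 5.28 and 3.76 on the log2 scale, inv1, for invertase, by 4.38 and gut2 by 4.38. The iron uptake genes fip1 and frp1 differed by -3.72 and -3.19, and pfl8, of the DIPSY flocculin family, by -3.91. Within replicates 2 and 3, limma on 2 arrays per medium called 200 genes higher and 252 lower in YEPME, 9 and 3 of them at least 2-fold, with 994 at an unadjusted p under 0.05. The call there rests on the YEPD arrays, with 19 genes left without YEPD replicate 2 and 20 without YEPD replicate 3. Of the 452 genes, 268 (59.3%) differed in the same direction in replicate 1, 100 of the 200 higher and 168 of the 252 lower genes. Over all genes the median difference was -0.042 in replicate 1, against 0.005 and 0.002 in replicates 2 and 3. A lower value in replicate 1 was therefore the more common one for any gene, called or not. The difference itself departed between the batches for 1344 genes in a limma interaction test. For 1203 of these the absolute difference was larger in replicate 1, a single pair, than in the mean of replicates 2 and 3. A single pair varies more than a mean, so this count cannot show a stronger response in replicate 1. Replicate 1 has 1 array per medium, so the interaction test and its p-values below assume that its arrays vary like those of replicates 2 and 3.

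**Figure D1:**
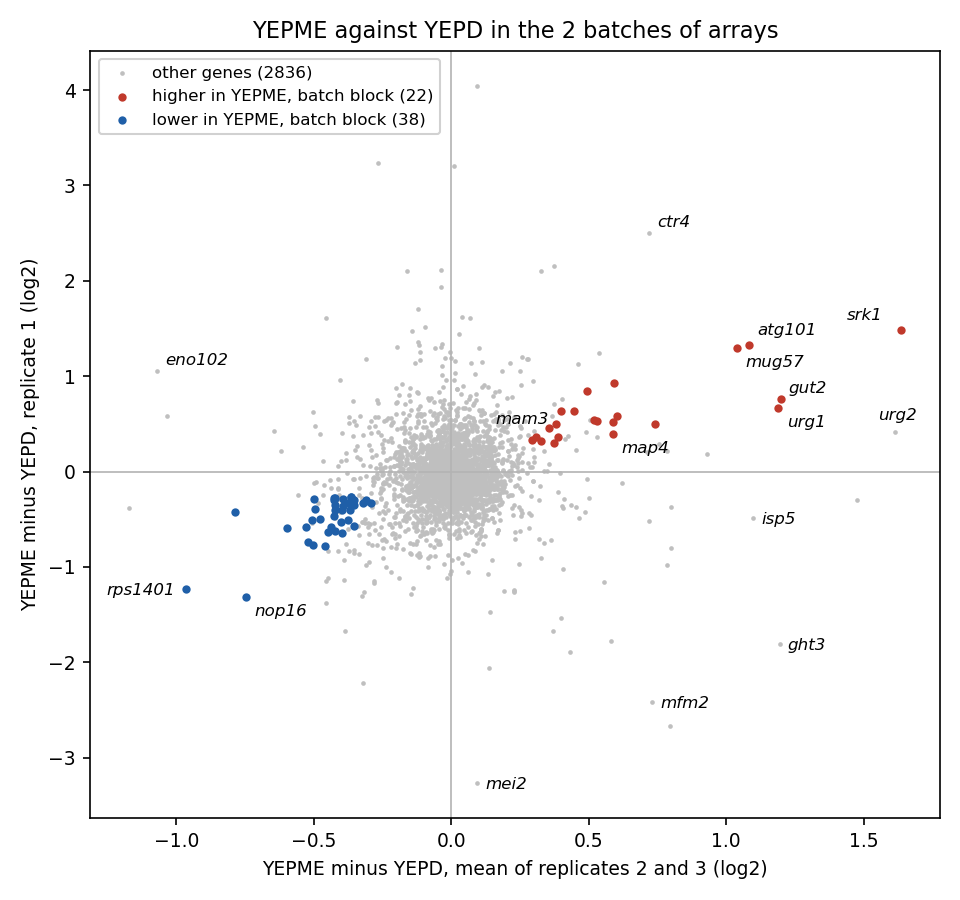
Log2 difference between YEPME and YEPD of each of 2896 genes, with the mean of replicates 2 and 3 on the horizontal axis and replicate 1 on the vertical axis; red and blue points are the 22 higher and 38 lower genes called with the batch as a block. Across all genes, which are not independent replicates, the values correlated at 0.102.

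Among mating genes, adhesins of both cell types were higher in YEPME. map4 (SPBC21D10.06C), the agglutination protein gene of P cells, rose by 0.52 ± 0.07 from 9.03 ± 0.35 to 9.55 ± 0.24 (SD, n = 3), and mam3 (SPAP11E10.02C), its M cell counterpart, by 0.38 ± 0.04 from 9.16 ± 0.14 to 9.54 ± 0.13; the adjusted limma p with the batch as a block was 0.0404 for both. Their differences were 0.39, 0.55 and 0.62 for map4 and 0.36, 0.39 and 0.38 for mam3 in replicates 1, 2 and 3. These 2 and pfl8 were the measured members of the 13 DIPSY flocculins and adhesins, and pfl8 differed by 0.00 ± 0.06 (adjusted p = 0.993). Adjusted over the list alone, the same count of 2 passed. The list was too short for a set test, and gsf2 and the other pfl genes were not analysed here.

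Of the 5 measured P cell genes, map4 and map3, the receptor gene for the M cell pheromone, rose, and 3 passed when adjusted over the list alone. map3 rose by 0.39 ± 0.05, while map2, for the P-factor precursor, differed by 0.28 ± 0.06, map1, for a transcription factor, by 0.18 ± 0.20 and sxa1 by 0.07 ± 0.05. The list was higher by camera with the batch as a block (median 0.28, adjusted p = 8.40e-04) and with no block (adjusted p = 0.00143). With an estimated correlation the adjusted p was 0.207 and 0.392. Within replicates 2 and 3, 4 of the 5 genes passed, and map1 differed by 0.49 there but by -0.43 in replicate 1 (interaction adjusted p = 0.00174).

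Of the 8 measured M cell genes, mam3 alone passed with the batch as a block, also when adjusted over the list alone. The others were lower in YEPME in replicate 1. Apart from mfm2, their mean differences over replicates 2 and 3 lay between -0.06 and 0.14. Single pairs reached 0.30 for mfm1 in replicate 3 and 0.23 for mam1 in replicate 2. The M-factor precursor gene mfm2 differed by -2.41 in replicate 1 and rose by 0.73 ± 0.05 within replicates 2 and 3 (limma, adjusted p = 0.00388; interaction adjusted p = 2.60e-04). mfm1 differed by -2.06 in replicate 1 and by 0.14 ± 0.09 within replicates 2 and 3, mam1, for the M-factor transporter, by -1.08 and 0.13 ± 0.05, and mam2, for the P-factor receptor, by -1.07 and 0.00 ± 0.04. The other mfm1 probe set differed by -2.51, -0.21 and 0.05 in replicates 1, 2 and 3. On the YEPME replicate 1 array mfm1 (5.66) lay close to the background limit (5.59), so the size of its difference there is uncertain. mfm3, mam4 and sxa2 differed by -0.87, -0.80 and -0.21 in replicate 1. The list median was -0.97 in replicate 1 and 0.10 over the mean of replicates 2 and 3, and camera did not pass with the batch as a block (adjusted p = 0.639), with no block (0.351) or within replicates 2 and 3 (0.0679). With no block and 1 array left out, it passed upward without YEPD replicate 1 (adjusted p = 0.0296) and downward without YEPD replicate 2 (0.0244) or YEPD replicate 3 (0.0135), and with an estimated correlation the adjusted p was 0.537, 0.863 and 0.767. Those fits ignore the batch and hold it in unequal shares in the 2 media, so they mix the difference between media with that between batches. The M-factor genes are near-copies of each other, so their probe sets can share signal.

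**Figure D2:**
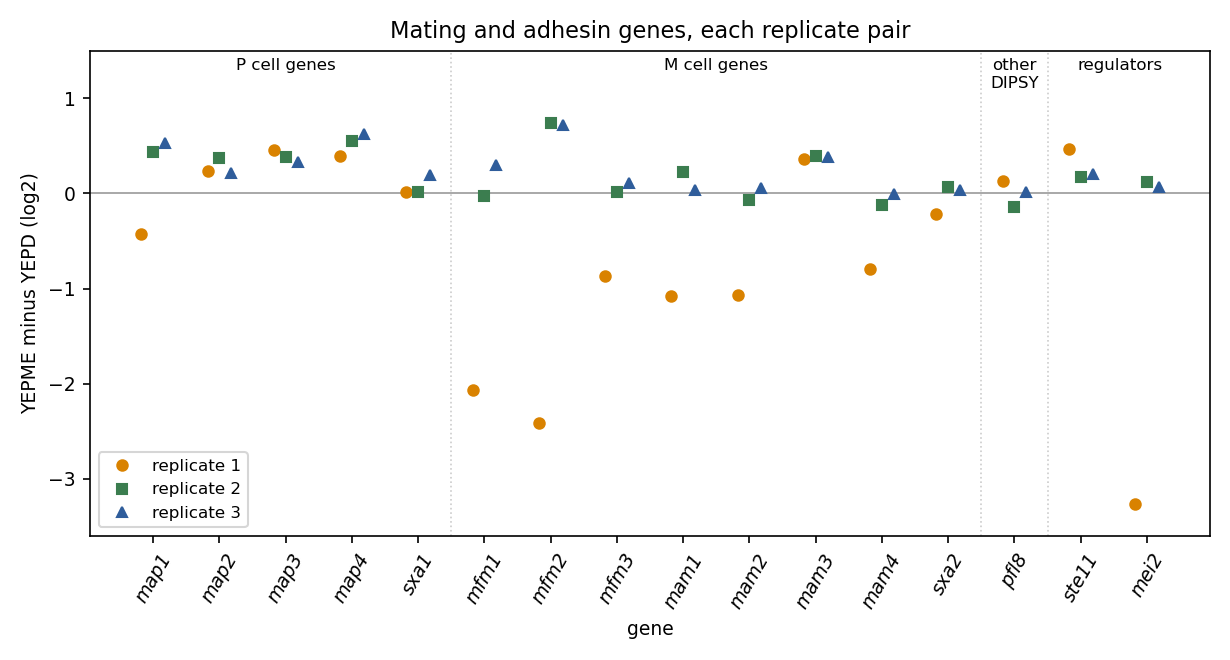
Log2 difference between YEPME and YEPD of each P cell, M cell and DIPSY gene measured and of ste11 and mei2, with a point for each replicate pair. map4 and mam3 lie between 0.36 and 0.62 in all 3 pairs, while mfm1, mfm2 and mei2 reach -2.06, -2.41 and -3.27 in replicate 1 alone.

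ste11, the transcription factor gene that switches on mating, differed by 0.28 ± 0.07 (adjusted p = 0.175 with the batch as a block) and by 0.47, 0.17 and 0.20 in the 3 pairs. Within replicates 2 and 3 it rose by 0.19 ± 0.04 (limma, adjusted p = 0.0373). mei2, for the RNA-binding protein that starts meiosis, differed by -3.27 in replicate 1 and by 0.09 ± 0.03 within replicates 2 and 3 (interaction adjusted p = 7.22e-05). Of the 18 pheromone signalling genes, 0 passed with the batch as a block, also when adjusted over the list alone, and 9 rose within replicates 2 and 3. Among those 9, rgs1, a negative regulator of the pathway, rose by 0.55 ± 0.07, the MAP kinase gene spk1 by 0.40 ± 0.04 and ste7 by 0.49 ± 0.04, whereas replicate 1 gave -1.16, -1.54 and -0.08. The list was higher by camera within replicates 2 and 3 (median 0.22, adjusted p = 2.80e-04), with the batch as a block (0.07, adjusted p = 0.0206) and with the replicate number as a block (adjusted p = 0.0216). It did not pass with no block (adjusted p = 0.179), and with an estimated correlation the adjusted p was 0.489, 0.244 and 0.375 for the 3 fits that passed. Of the 17 cell and nuclear fusion genes, 0 passed, 1 rose and 2 fell when adjusted over the list alone, and camera gave an adjusted p of 0.614. Of the 18 flocculation regulators, lkh1, for a LAMMER kinase, rose by 0.33 ± 0.04, also when adjusted over the list alone, and camera gave an adjusted p of 0.198.

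Among 20 genes of nitrogen starvation and uptake, urg1 was the member that passed with the batch as a block, 5 rose when adjusted over the list alone, and 12 rose and 1 fell within replicates 2 and 3. There urg2, for uracil phosphoribosyltransferase, rose by 1.61 ± 0.05, isp5, for an amino acid permease, by 1.10 ± 0.03 and isp7 by 0.80 ± 0.06, and in replicate 1 they differed by 0.41, -0.49 and -0.37. The list passed camera with no block (median 0.14, adjusted p = 0.00149) and with the batch as a block (adjusted p = 0.00690). With an estimated correlation the adjusted p was 0.724 and 0.510.

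Of the 19 glucose-repressed and alternative carbon genes, gut2 rose with the batch as a block, 3 rose when adjusted over the list alone, and 9 rose and 1 fell within replicates 2 and 3. dak2, for dihydroxyacetone kinase, rose there by 1.48 ± 0.11 and ght3, of the hexose transporter family, by 1.19 ± 0.06, and replicate 1 gave -0.30 and -1.81. Camera passed with the batch as a block (median 0.15, adjusted p = 0.00609; adjusted p = 0.207 with an estimated correlation) and not with no block (adjusted p = 0.119). ght1, inv1 and gut2, whose levels differed between the batches, belong to this list. Of the 7 genes for alpha-glucoside and starch breakdown, 0 passed, 1 rose when adjusted over the list alone, and camera gave an adjusted p of 0.0328 (adjusted p = 0.252 with an estimated correlation) and of 0.119 with no block.

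Of 29 stress response genes, ctt1, for catalase, rose by 0.70 ± 0.09 and gst2, for a glutathione transferase, by 0.51 ± 0.06, and 4 rose when adjusted over the list alone. Camera with the batch as a block gave a median of 0.12 and an adjusted p of 2.72e-04 (adjusted p = 0.207 with an estimated correlation), and with no block the list did not pass (adjusted p = 0.169). Within replicates 2 and 3, 11 of the 29 genes rose and 2 fell. Among those that fell, srx1 differed by -0.50 ± 0.03 there and by 0.62 in replicate 1. Of 23 genes for autophagy and vacuolar proteases, atg101 and atg22, for a vacuolar amino acid exporter, rose by 1.16 and 0.48, and 3 rose and 1 fell when adjusted over the list alone. Camera gave a median of 0.11 and an adjusted p of 8.40e-04 (adjusted p = 0.207 with an estimated correlation). cmk2, another kinase of the stress pathway, rose by 0.66 ± 0.07.

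Over all 6 arrays, ribosome assembly and RNA polymerase I genes had the lowest median of the lists (-0.31), while in replicate 1 the M cell (-0.97) and mitosis (-0.48) lists lay lower. Of 33 genes, 7 fell with the batch as a block, 21 when adjusted over the list alone and 30 within replicates 2 and 3, and 0 rose in any of these. Besides nop16, the RNA helicase gene dbp3 differed by -0.57 ± 0.08, the RNA polymerase I subunit gene rpa34 by -0.49 ± 0.05 and brx1 by -0.46 ± 0.05. The list median was -0.30 in replicate 1 and -0.32 over replicates 2 and 3, but 12 of the 33 genes were higher in YEPME in replicate 1. Camera gave an adjusted p of 7.45e-12 with the batch as a block and 0.00453 with no block, and with an estimated correlation the adjusted p was 0.124 and 0.856. mis3, ppp1 and ctu1, outside this list, fell by 0.59 ± 0.07, 0.51 ± 0.07 and 0.59 ± 0.07; mis3 and ppp1 act in ribosome assembly and ctu1 in tRNA thiolation.

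Of 119 cytosolic ribosomal protein genes, 13 fell with the batch as a block, 15 when adjusted over the list alone and 17 within replicates 2 and 3, while the list median was 0.00 and its mean -0.06. In replicate 1, 86 of the 119 genes were higher in YEPME, with a median of 0.03. Besides rps1401, rpl1603 differed by -0.66 ± 0.09, rps1001 by -0.59 ± 0.06, rpl3201 by -0.55 ± 0.05 and rps1002 by -0.51 ± 0.04, against 0.03 ± 0.04 for rps13 and 0.01 ± 0.04 for rpl1001. Many of these genes have a near-identical copy, so a probe set can also bind the RNA of the copy. As a set they passed camera with no block (adjusted p = 0.00700) and not with the batch as a block (adjusted p = 0.258), and with an estimated correlation the adjusted p was 0.856 and 0.867. Within replicates 2 and 3 the list passed camera downward (adjusted p = 0.00395, and 0.489 with an estimated correlation). Its largest fall there, rpl3202 with -1.03 ± 0.03, differed by 0.58 in replicate 1.

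**Figure D3:**
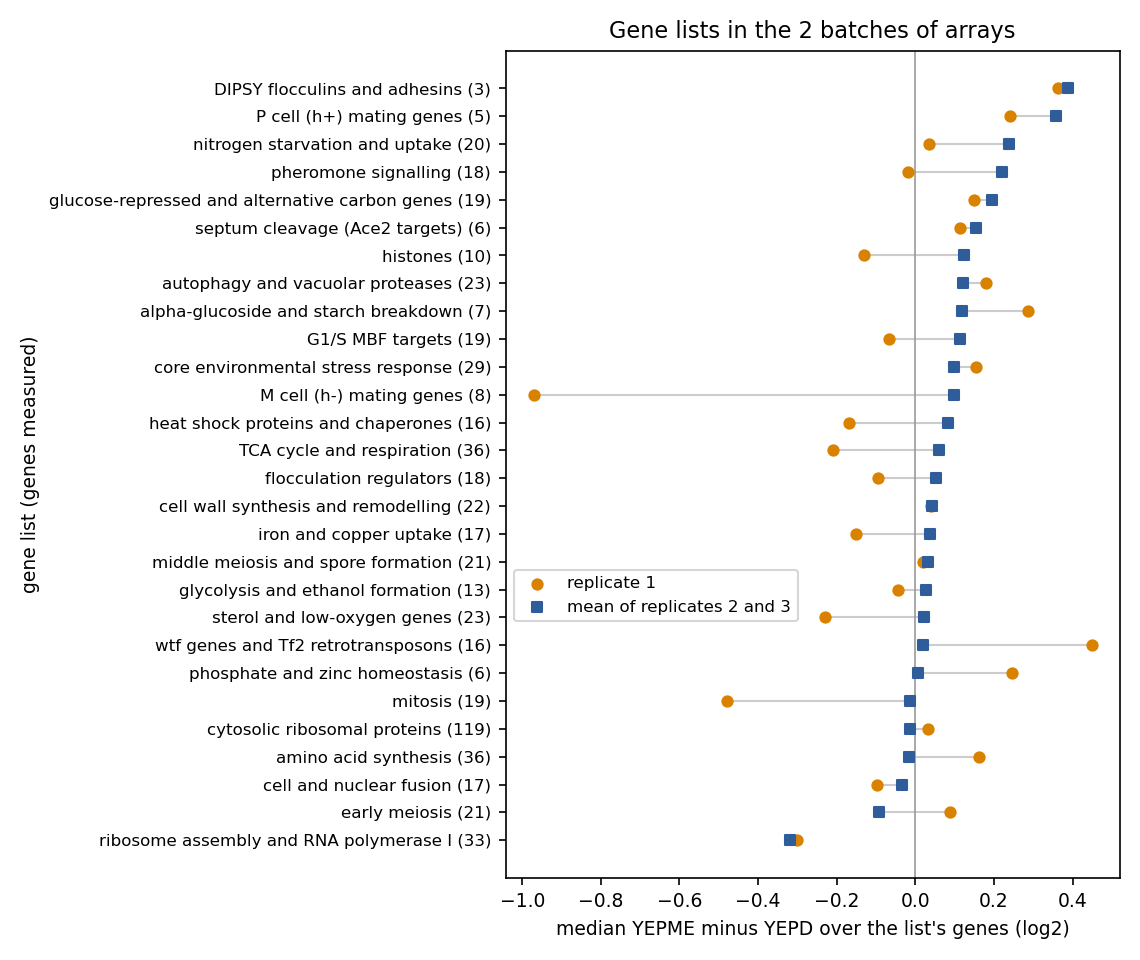
Median log2 difference between YEPME and YEPD over the genes of each of the 28 lists, with circles for replicate 1, squares for the mean of replicates 2 and 3, and the number of genes measured in brackets. Ribosome assembly lies at -0.30 and -0.32, while the M cell list lies at -0.97 in replicate 1 and 0.10 in replicates 2 and 3.

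Among 21 early meiosis genes, mei4, for a meiotic transcription factor, rose by 0.60 ± 0.05, rec8, for the meiotic cohesin, by 0.56 ± 0.08 and rec10 by 0.32 ± 0.04, and 4 rose and 2 fell when adjusted over the list alone. The median of the list was -0.09 and its mean -0.03 while its camera direction was upward (adjusted p = 0.826). mug2 and mug97 rose by 0.53 ± 0.04 and 0.53 ± 0.06. The YEPD values of rec8 (5.63, 5.01 and 5.02) lay close to the background limits of their arrays (5.60, 4.78 and 4.80). On the YEPD replicate 1 array, mug97 (5.50) lay below that limit, so the sizes of these 2 rises are uncertain. Of 21 genes of middle meiosis and spore formation, 0 passed, 4 rose and 4 fell when adjusted over the list alone, and camera gave an adjusted p of 0.649. Of 22 cell wall genes, the cell integrity MAP kinase gene pmk1 rose by 0.42 ± 0.05, 2 rose when adjusted over the list alone, and camera gave an adjusted p of 0.0206 (adjusted p = 0.244 with an estimated correlation) and of 0.118 with no block. Of 17 iron and copper genes, ctr5, for a copper transporter subunit, rose by 0.61 ± 0.09 and the ferric reductase gene frp2 fell by 0.40 ± 0.05. When adjusted over the list alone 4 rose and 7 fell, and the median was 0.06 while the mean was -0.01 and the camera direction downward (adjusted p = 0.770). Septum cleavage genes passed camera as a set of 6 (median 0.15, adjusted p = 0.0134; adjusted p = 0.252 with an estimated correlation) but not with no block (adjusted p = 0.0744), with 0 single genes past the test and 1 higher when adjusted over the list alone. The 16 wtf and Tf2 genes passed as a set (median 0.21, adjusted p = 0.0152; adjusted p = 0.541 with an estimated correlation), with 0 single genes past the test, also when adjusted over the list alone. Their median was 0.45 in replicate 1 and 0.02 over replicates 2 and 3.

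In the remaining 9 lists, 0 genes passed limma and camera called no list with the batch as a block. Camera gave an adjusted p of 0.921 for 13 genes of glycolysis and ethanol formation (median 0.00, mean -0.03, camera direction upward), 0.50 for 36 of the TCA cycle and respiration, 0.207 for 16 of heat shock proteins and chaperones and 0.413 for 23 sterol and low-oxygen genes. It gave 0.310 for 10 histone genes, 0.109 for 19 mitosis genes and 0.109 for 36 amino acid synthesis genes, and in these 7 lists 0 genes also passed when adjusted over the list alone. Among 6 phosphate and zinc genes 1 rose when adjusted over the list alone (camera adjusted p = 0.109), and among 19 targets of the G1/S factor MBF 2 rose (camera adjusted p = 0.225). Within replicates 2 and 3, camera put the TCA cycle, heat shock and MBF lists higher (adjusted p = 0.00877, 0.00210 and 0.00541; adjusted p = 0.489 for each with an estimated correlation), with 0, 5 and 4 genes higher and 0, 0 and 2 lower. In replicate 1 the medians of these lists were -0.21, -0.17 and -0.07. The mitosis genes had a median of -0.48 in replicate 1 and -0.01 over replicates 2 and 3.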

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

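The tests on the S. cerevisiae LEU2 probe set, the fits with the batch as a block and the count after exchanging the replicate 1 arrays were chosen only after the result was seen.

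The difference between YEPME and YEPD itself differed between replicate 1 and replicates 2 and 3 for 1344 genes (limma interaction, adjusted p under 0.05), on the assumption that the 1 array per medium in replicate 1 varies like the arrays of replicates 2 and 3. The authors' normalization stays open as a cause. After quantile normalization of all 6 arrays together, the correlation across genes between the batches' differences was 0.101, against 0.102 before. That step starts from summarised values of arrays that already share a scale within each batch. It could hardly change these differences, so it cannot decide. Noise of single probe sets was set against random lists, and 12 of 27 lists had a replicate 1 median outside their central 95%. Some of these, such as ribosome assembly (-0.30 in replicate 1 and -0.32 over replicates 2 and 3), were alike in both batches. Those do not bear on the departure. Noise alone is argued against for lists that did depart, such as mitosis (-0.48 and -0.01), TCA cycle (-0.21 and 0.06) and amino acid synthesis (0.16 and -0.02). An exchange of the 2 replicate 1 arrays stays open. Of the genes called within replicates 2 and 3, 59.3% had the same direction in replicate 1, as 100 of 200 higher and 168 of 252 lower genes. That lies between the bounds set in advance (40% and 60%). The bounds took no account of the median of -0.042 over all genes in replicate 1. With the arrays exchanged, the batch-blocked limma fit called 1 gene against 60, while 383 against 478 genes had an unadjusted p under 0.05. Another state of the cultures, another strain or another handling in replicate 1 stays open too, as the labels record none of these and they were not tested.

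The probe set for S. cerevisiae LEU2, outside the S. pombe genes compared, gave 12.125 on the YEPD replicate 1 array and 10.729 on the YEPME replicate 1 array, against 4.061 to 5.245 on the other 4. S. cerevisiae RNA is argued against, since abundant S. cerevisiae transcripts rose in replicate 1 by -0.077 relative to all S. cerevisiae probe sets. Higher background and S. pombe leu1 RNA are argued against too, since the highest rise of any other S. cerevisiae probe set was 2.348 and that of leu1 was 0.152, against 6.891 for LEU2. A LEU2 marker gene in the replicate 1 strains was not tested: that the lowest replicate 1 value exceeded the highest other by 5.484 on the log2 scale is the observation itself. The labels give the same strain names for all arrays and no genotype, and no biological explanation was tested.

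The probe set for S. cerevisiae STE11, also outside the comparison, was higher in YEPME by 2.419 on average and by 3.073, 1.901 and 2.282 in replicates 1, 2 and 3. Its YEPD values (4.349, 4.109 and 3.984) lay below the background limit of their arrays. These differences can at most be read as lower bounds for whatever RNA bound the probe set, and which RNA bound it was not tested.

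Among 2198 unnamed probe sets above background on at least 3 arrays, 26 passed limma with the batch as a block, 7 higher and 19 lower in YEPME. The largest differences were 3.13 for 1772453_at, 1.63 for 1773396_at, -0.98 for 1778894_at and -0.85 for 1770100_at.

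With no block, 10 of 10 splits of the 6 arrays gave as many genes as the real one, both in all and at least 2-fold, since the real split and the highest other each gave 0. Splits that put both replicate 1 arrays in 1 group gave 109 to 566 genes at an unadjusted p under 0.05 against 32 for the real one, which points to the batch. With the batch as a block, 1 of 6 splits, the real one, gave as many genes, 60 against a highest other of 1. That other split, which exchanges the replicate 1 arrays, had 383 genes at an unadjusted limma p under 0.05 against 478 for the real one. The remaining splits had 16 to 40. Neither number of splits can give a share under 0.05.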

How the results depend on the processing

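The fits with the batch as a block and within replicates 2 and 3, and every alternative to those fits, were chosen only after the data were seen. With no block, limma called 0 genes under each alternative chosen before the data were examined, with 317 at an unadjusted p under 0.05 with the replicate block and 19 to 66 under the others. With the batch as a block it called 60 genes, 6 of them at least 2-fold, and within replicates 2 and 3 it called 452 and 12.

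With the replicate block in place of the batch, the 60 became 0, and within replicates 2 and 3 the 452 became 695. Pheromone signalling (median 0.073) passed camera with the replicate block and with the batch as a block, and also within replicates 2 and 3 (0.22); with an estimated correlation the adjusted p was 0.375, 0.244 and 0.489. Against no block, the replicate block gave a call to the glucose-repressed, alpha-glucoside, stress, septum and cell wall lists (adjusted p of 0.373 to 0.375 with an estimated correlation) and ended that of the ribosomal proteins. None of the 164 named genes passed with either, and the 34 that passed with the batch as a block did not pass with the replicate block. Centring, normalizing again, filtering, averaging probe sets, using every probe set, and trend and robust variance gave 53 to 60 genes with the batch as a block. Of the 60 first called, 47 were called again after normalizing again and 52 with trend and robust variance. Within replicates 2 and 3 these alternatives gave 446 to 503, apart from 753 with trend and robust variance. There 52.7% were higher in YEPME with centred arrays against 44.2%, so the balance of directions follows the scaling.

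With the batch as a block, a fit without 1 of the replicate 1 arrays is the same as the fit within replicates 2 and 3. The block absorbs the array that is left, so its 452 genes do not show how the call depends on replicate 1. Leaving out 1 array of replicates 2 and 3 at a time gave 0 genes with the batch as a block. Within replicates 2 and 3 it gave 19 to 483, with 19 without YEPD replicate 2 and 20 without YEPD replicate 3. A lone array was assumed to vary like the other group.

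The P cell list (0.277) and the nitrogen list (0.139) lost their call with an estimated correlation (adjusted p = 0.392 and 0.724) and with fry (0.219 and 0.959). The M cell median was 0.098 within replicates 2 and 3. With 1 array left out and no block, the batches are unequal between the media and mix into these values: medians ran from 0.154 to 0.404 for P cell genes, -0.555 to 0.304 for M cell genes, 0.013 to 0.145 for pheromone signalling, -0.042 to 0.068 for fusion, 0.137 to 0.277 for nitrogen, -0.269 to 0.878 for glucose-repressed, -0.090 to 0.411 for alpha-glucoside, -0.313 to 0.351 for the TCA cycle, -0.310 to 0.609 for stress, -0.756 to 0.135 for ribosome assembly, -0.072 to 0.106 for amino acid synthesis and -0.064 to 0.213 for autophagy. The median of 19 of 27 lists turned sign without some array: M cell, TCA cycle and amino acid genes among others without YEPD replicate 1, and stress, ribosome assembly, autophagy, glucose-repressed and alpha-glucoside genes among others without YEPME replicate 1. The nitrogen call ended without YEPME replicate 2 (0.181) or 3. Within replicates 2 and 3 the TCA cycle (0.060), meu7 (0.232), mfm2 (0.731), rgs1 (0.554), spk1 (0.398), ste6 (0.339) and sti1 (0.319) were higher (adjusted p = 0.489 with an estimated correlation for the TCA cycle), while over all 6 arrays they did not pass and lay at -0.32 to -0.02. For these results the cause was not tested.

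Leaving out the list members that entered through an older synonym took flocculation regulators within replicates 2 and 3 from an adjusted p of 0.0564 to 0.0242 (adjusted p = 0.515 with an estimated correlation). Signal over background limits the dimmest genes: 2863 of 2896 lay above it. Unnamed probe sets could not join the fit of every probe set.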

Other observations

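The test on mug genes was chosen only after the result was seen; that on chromosome ends was planned. The hypothesis that genes named mug (meiotically upregulated genes) are higher in YEPME as a set was tested with camera on 91 genes with the batch as a block, a limma set test, which gave an adjusted p of 0.338 over the 2 hypotheses (0.1689 before adjustment). Of these genes, 3 were higher and 0 lower in YEPME by limma with the batch as a block, and 13 higher and 8 lower within replicates 2 and 3. The hypothesis that genes near the ends of chromosomes I and II move as a set was tested on 48 genes in the same way and gave an adjusted p of 0.631 (0.6306 before adjustment). Of these genes, 0 were higher and 1 was lower by limma with the batch as a block, and 15 were higher and 11 lower within replicates 2 and 3. Over all 2896 genes, 200 were higher and 252 lower within replicates 2 and 3, a smaller share. Camera tests for a shift in a shared direction, so it cannot decide whether members move both ways.

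The control probe sets also differed between the batches: replicate 1 minus replicates 2 and 3 was -1.90 for bioB, 2.26 for lys, 1.60 for phe, 1.74 for thr, 1.78 for dap and 0.50 for cre on the log2 scale.

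Some large differences of replicate 1 were chosen after their values were seen. pyp2, for a phosphatase of stress MAP kinases, differed by 4.05 in replicate 1 and by 0.10 within replicates 2 and 3 (limma interaction, adjusted p = 1.73e-04).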
